A study of Mus musculus with 6 samples.

How the data were processed

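RNA was measured in 6 pulldown libraries of mouse quiescent neural progenitor cells, 3 from cells given EU and 3 from cells given PBS, named by the group and number in the labels. Per the labels, genomic DNA was removed with DNase I before the pulldown and libraries were made with a total RNA kit. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The authors deposited one table of whole-number read counts for 55416 Ensembl gene IDs, with no normalization. The submitters' processing notes name bcl2fastq 2.20.0, UMI-tools 1.1.2, STAR 2.7.10b and featureCounts 2.0.1 and the build GRCm39, without roles; UMI (molecular identifier) counting is read from the name of the deposited sheet and from UMI-tools being listed. The strand setting and the handling of reads with several matches are not given in the sources used here, so values of near-identical gene copies and of overlapping or antisense genes are uncertain. All 6 columns belong to a sample and 0 rows name no gene.

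Gene IDs were matched to GENCODE release M21 for symbols, classes, lengths and transcript sequences only. Of the IDs, 52083 matched a symbol and 3281 matched no class. That release uses an earlier build than the counts, and no coordinates are given for this reason. Counts differed between replicates of each group by far more than sampling noise, so no library is a copy of another.

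The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM factors, filterByExpr (12477 genes kept) and group as the only term. Adjusted p-values are Benjamini-Hochberg with a threshold of 0.05. Gene lists and classes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, two-sided, for lists of at least 5 and classes of at least 20 tested members. Totals, detected genes, class shares and summed lists were compared by exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1. CPM values of single genes and of the fixed gene lists are scaled by the TMM factors and folds are EU over PBS. The sums over satellite-like models, the chemoreceptor shares, the class shares and the CPM worth of 3 counts are over library totals without TMM factors. Where PBS held no count, the fold is a lower bound against 3 counts over the group. A count of 3 was worth 0.113 to 0.314 CPM in the EU libraries and 4.11 to 7.26 CPM in the PBS libraries, so low genes were not measurable in PBS. Floors cover counting error only, and the bootstrap intervals of list medians cover the spread between members only.

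Named genes followed a rule fixed before the data were examined. It took up to 10 genes per direction with the largest folds among those with adjusted p below 0.05, a mean of at least 5 CPM and separated groups, and up to 3 predicted genes per direction under the same conditions. It also took the 4 members of each list with the smallest p, the 5 most abundant genes of each group, and Malat1, Neat1, Meg3, Kcnq1ot1, Xist, Sox2, Nes, Gfap, Id1 and Mki67; Meg3 was not among the tested genes and has no value. Values of other genes in the closing section, and of mt-Co1, mt-Nd1, mt-Nd6 and single pseudogenes, were chosen after they were seen.

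Each test was tried on simulated counts with 200 changed genes. When both groups had the noise of the EU libraries, edgeR recovered 13, 43, 48 and 50 of 50 genes changed 2-, 4-, 8- and 16-fold, with 3 calls among unchanged genes. When each group had its own noise (common dispersion 0.058 in EU and 0.912 in PBS), edgeR recovered 0 at every size. All genes of a group shared that 1 dispersion, whereas the spread of the real PBS values differed between genes. The simulation with each group's own noise was run first, and the one with EU noise was added after it recovered no gene. DESeq2 1.42.0 then recovered 7, 25, 38 and 43 of 50, but 531 of its calls, 82.1%, were unchanged genes. Limma-voom recovered 0, 0, 0 and 4 with 2 unchanged genes called (33.3% of its calls), and with group weights 0, 3, 9 and 28 with 21 (33.9%). The simulated shift of a list gave camera p = 1.1e-04 with the preset and 0.077 with an estimated correlation under that noise, and 3 of 50 unchanged lists fell below 0.05. The simulated genes varied independently, so this number does not cover lists whose genes vary together. Among the called lists the estimated correlation ran from -0.092, in mitochondrial ribosomal and transfer RNAs, to 0.73, in mitochondrial protein-coding genes.

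Alternatives fixed beforehand were the replicate number as a block, DESeq2 size factors, library size alone, upper-quartile factors, 2 other low-count filters, leaving out each library, DESeq2, limma-voom, fry, an estimated correlation and exonic length. Unscaled counts, thinned libraries, leaving out the most abundant gene, a filter at a mean of 50 CPM, limma-voom with group weights and summed lists were added after seeing the data.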

Results

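Gene-level RNA counts were collected from mouse neural progenitor cells of embryonic brain origin that were held in quiescence with FGF2 at 10 ng/ml and BMP4 at 20 ng/ml. EU (5-ethynyluridine), a uridine analogue that cells build into newly made RNA, was given at 250 µM on day 1 after quiescence began, and cells were harvested for RNA on day 8. RNA that still carried EU after these 7 days was coupled to biotin and pulled down on streptavidin beads. Cells given PBS, the vehicle, went through the same pulldown and measured what binds without label. There were 3 EU and 3 PBS libraries, and the comparison asks which RNAs made at the start of quiescence were still present 7 days later, above background binding.

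EU pulldowns yielded far more RNA counts than vehicle pulldowns. The 3 EU libraries held 9564856, 26479031 and 23527595 counts and the 3 PBS libraries 647416, 413181 and 729649, so that the mean of the EU totals was 33.3 times that of the PBS totals. The lowest EU total lay 13.1 times above the highest PBS total (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). At least 10 counts were reached by 15671 ± 1452 genes in EU and 7000 ± 785 genes in PBS (SD, n = 3 each). Once all libraries were thinned to 413181 counts, 5772 ± 589 genes in EU and 6027 ± 183 genes in PBS reached 10 counts (exact permutation p = 0.6), whereas 13525 ± 189 and 10727 ± 415 genes had any count (exact permutation p = 0.1). The most abundant gene, ENSMUSG00000119584, whose ID is not paired with a symbol in the annotation used, took 15.1% ± 5.76 of EU counts and 16.4% ± 3.33 of PBS counts. Malat1, an abundant nuclear long noncoding RNA, came next in both groups. Without any scaling, 12174 of 12477 tested genes were higher and 1 was lower in EU (edgeR, adjusted p below 0.05). The number of counts in a library also depends on how it was amplified and sequenced, so all further folds compare shares of a library, scaled by TMM factors.

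**Figure D1:**
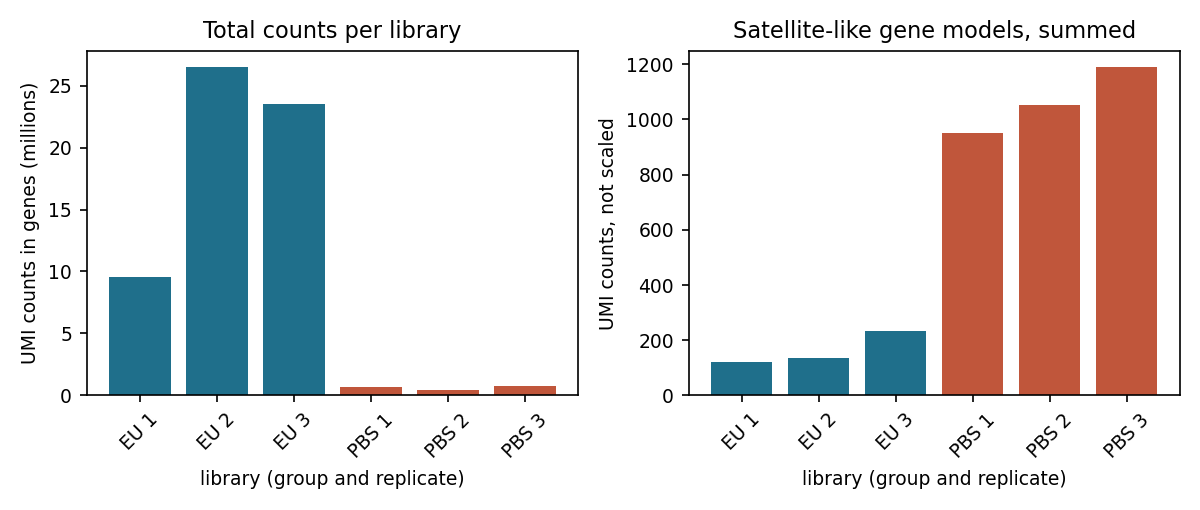
Bars give, for each of the 6 libraries, the total UMI counts in genes (left) and the unscaled UMI counts summed over 11 satellite-like gene models (right), with EU libraries in blue and PBS libraries in red. The PBS libraries hold 413181 to 729649 counts in all, against 9564856 to 26479031 in EU, yet 952 to 1189 satellite-like counts against 120 to 234.

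Scaled to library composition, 3 genes differed between the pulldowns and all 3 were lower in EU. These were the predicted protein-coding gene models Gm10800, Gm10801 and Gm10718. Gm10800 (ENSMUSG00000075014) measured 7.28 ± 3.93 CPM in EU and 1444 ± 265 CPM in PBS (SD, n = 3), a log2 fold of -7.66 ± 0.53 (SE; edgeR adjusted p = 0.0060). Gm10801 (ENSMUSG00000075015) had a log2 fold of -7.60 ± 0.62 (edgeR adjusted p = 0.0113) and Gm10718 (ENSMUSG00000095186) one of -7.08 ± 0.68 (edgeR adjusted p = 0.0210). The 3 models share sequence with one another and with 8 further models, so reads cannot be assigned to one member with certainty. Summed over the 11 models, EU libraries held 9.21 ± 3.76 CPM and PBS libraries 1881 ± 579 CPM of their totals, here without TMM factors, and the unscaled counts were also higher in PBS, at 952, 1051 and 1189 against 120, 136 and 234. Without EU replicate 1 the number of genes called lower was 10, without PBS replicate 1, PBS replicate 2 or PBS replicate 3 it was 0. With library size alone as the scaling 3 genes were called higher and 34 lower.

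No gene was called higher in EU in the main edgeR fit, which had group as the only term. In that fit 1571 genes were higher at an unadjusted p below 0.05, and the smallest adjusted p was 0.098. With the replicate number as a block edgeR called 144 higher and 50 lower, and without a low-count filter 82 and 262. Whether equal numbers were pairs is not in the labels and stays open. DESeq2 called 506 genes higher and 438 lower, limma-voom 214 higher and 25 lower, and limma-voom with 1 variance weight per group 668 higher and 31 lower. The calls that DESeq2 and limma-voom shared numbered 190, with 170 higher in EU, and 158 of those 170 had no count in any PBS library. The 3 EU libraries all lay above the 3 PBS libraries for 2715 of 12477 genes and all below for 799, together 28.2% where chance gives 10% for equally noisy groups. Chance gives more where one group is noisier, as PBS was, so this share is not read as an excess. Replicates of PBS resembled each other less (Pearson correlation of log2 CPM across genes 0.630 to 0.663) than replicates of EU (0.946 to 0.986), and EU and PBS libraries correlated at 0.712 to 0.783. On simulated counts with 1 dispersion for all genes of a group, edgeR recovered 0 of 50 genes at each of 2-, 4-, 8- and 16-fold. At such noise the absence of calls does not show that folds were small. On the same counts unchanged genes made up 82.1% of the calls of DESeq2, 33.3% of those of limma-voom and 33.9% of those of limma-voom with group weights. Real PBS noise differed between genes, as in Fasn at 618 ± 21.8 CPM and Gfap at 3625 ± 3306 CPM, and edgeR did call 3 genes. The shares from the simulation are therefore not rates for the real calls.

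Several genes named by the fixed rule had separated groups without passing the test. Ncan, a chondroitin sulphate proteoglycan of neural extracellular matrix, measured 19280 ± 2464 CPM in EU and 6689 ± 2025 in PBS (SD, n = 3; log2 fold 1.53 ± 0.25 SE, edgeR adjusted p = 0.103). Fasn, the fatty acid synthase, measured 1529 ± 267 and 618 ± 21.8 CPM (edgeR adjusted p = 0.098). Foxo3, a transcription factor tied to stem cell quiescence, measured 272 ± 40.1 and 105 ± 9.40 CPM, and the BMP target Id1 86.5 ± 28.8 and 14.8 ± 6.17 CPM (edgeR adjusted p = 0.103 each). In the other direction, Miat, a nuclear long noncoding RNA, measured 94.4 ± 12.1 CPM in EU and 283 ± 59.3 in PBS, and the astrocyte filament gene Gfap 346 ± 309 and 3625 ± 3306 CPM (edgeR adjusted p = 0.103 each). Much of the Gfap value came from PBS replicate 1, at 7440 CPM against 1848 and 1589 in PBS replicates 2 and 3. Sox2, a neural stem cell transcription factor, was close to equal at 316 ± 57.2 and 346 ± 53.7 CPM, as was Kcnq1ot1 at 204 ± 35.2 and 189 ± 63.4 CPM. Nes, an intermediate filament of progenitors, measured 73.1 ± 2.77 and 37.2 ± 28.8 CPM.

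Of 25 gene lists fixed before the data were examined, 20 had at least 5 tested members and 7 passed limma's camera test with a preset correlation of 0.01, 4 lower and 3 higher in EU. No list passed with an estimated correlation, where the smallest adjusted p was 0.238. List medians are given relative to the median log2 fold of all tested genes, which was 0.15 with TMM factors and shifted by -0.17 with library size alone. When a library was left out the low-count filter was redone. It kept 8299 to 8670 genes without an EU library and 14339 to 14418 without a PBS library. For lists too, the effect of a library cannot be told from that of the filter.

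Messenger RNAs known for introns detained in the nucleus were lower in EU as a group, with 22 of 30 members at a negative fold and a median 0.63 below that of all genes (-0.63; camera adjusted p = 9.3e-06; adjusted p = 0.238 with an estimated correlation). Their summed abundance was 3545 ± 215 CPM in EU and 4712 ± 277 in PBS (SD, n = 3; exact permutation p = 0.1). Luc7l3, a splicing-associated protein gene, measured 70.9 ± 3.57 CPM in EU and 185 ± 65.9 in PBS, and Ogt, the O-GlcNAc transferase, 180 ± 28.9 and 371 ± 87.5 CPM, while Luc7l2 went the other way at 209 ± 26.5 and 114 ± 26.2 CPM. None of the 30 passed over all genes and 2, both lower, passed when adjusted over the list alone. Nuclear long noncoding RNAs were lower by camera (median -0.53, 10 of 19 negative, 1 passing lower over the list alone, adjusted p = 0.035; adjusted p = 0.354 with an estimated correlation). Xist, the X-inactivation RNA, measured 1339 ± 178 and 1934 ± 225 CPM and Neat1, the paraspeckle scaffold, 17.9 ± 3.55 and 78.7 ± 69.3 CPM, where the groups overlapped (PBS replicates 1 to 3 at 144.7, 85.1 and 6.44 CPM). Malat1 measured 27360 ± 5189 CPM in EU and 20340 ± 2598 in PBS (edgeR adjusted p = 0.320), and because of it the summed list was higher in EU, at 29520 ± 5323 against 23500 ± 2289 CPM (exact permutation p = 0.2). The call of this list was lost without EU replicate 2 (adjusted p = 0.055), without PBS replicate 1 (0.093) and without PBS replicate 2 (0.124).

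Mitochondrial protein-coding genes were lower by camera (median -0.26, adjusted p = 1.7e-04; adjusted p = 0.645 with an estimated correlation), with 7 of 13 members negative and, over the list alone, 2 passing higher and 6 lower. The list was mixed, and its most abundant member, mt-Co1, measured 11680 ± 1672 CPM in EU and 8738 ± 814 in PBS. The 2 members passing higher were mt-Nd1 (5071 ± 626 and 3689 ± 395 CPM) and mt-Nd6 (700 ± 63.9 and 286 ± 209 CPM), with mt-Cytb measuring 9706 ± 1379 CPM in EU and 9553 ± 848 in PBS and mt-Nd5 9448 ± 1322 and 10200 ± 1280. Low members lay below PBS, such as mt-Atp6 (17.6 ± 11.99 and 214 ± 43.9 CPM), mt-Co2 (18.2 ± 12.9 and 148 ± 12.3 CPM) and mt-Co3 (13.1 ± 9.73 and 123 ± 24.1 CPM). Nuclear copies of mitochondrial sequence can take reads from these genes, so their values are uncertain, and the summed list was 46320 ± 6345 and 41650 ± 4486 CPM (exact permutation p = 0.4). Cytosolic ribosomal protein genes were lower by camera with 47 of 77 negative and none passing over the list alone (median -0.22, summed 4946 ± 290 and 5286 ± 768 CPM, adjusted p = 0.017; adjusted p = 0.518 with an estimated correlation). That call was lost without EU replicate 1 (adjusted p = 0.118), EU replicate 2 (0.252), EU replicate 3 (0.442) or PBS replicate 2 (0.124). The mitochondrial ribosomal and transfer RNAs were higher (5 of 6 positive, all 5 passing over the list alone, summed 47970 ± 23410 and 18490 ± 5357 CPM, adjusted p = 0.0027; adjusted p = 0.238 with an estimated correlation). The call was lost without PBS replicate 1 (adjusted p = 0.086). Leaving out any EU library left fewer than 5 tested members, so the list was not tested there. The ribosomal RNA mt-Rnr1 measured 26760 ± 12430 CPM in EU and 9786 ± 2969 in PBS, and mt-Rnr2 21190 ± 11050 and 8701 ± 2401 CPM. The fitted median of this list, 4.55, fell to 1.37 when the 3 members at 0 in PBS were set to the bound of 3 counts over the group. Those members, mt-Tl1, mt-Tp and mt-Tw, were among the 5 that passed, at 8.75, 4.76 and 2.53 CPM in EU. They entered the test only through their EU counts, at levels hardly measurable in PBS.

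Replication-dependent histone genes, whose transcripts lack a poly(A) tail, were higher in EU, with 40 of 48 at a positive fold (median 1.64 above all genes, adjusted p = 9.3e-06; adjusted p = 0.527 with an estimated correlation). Their summed abundance was 1076 ± 466 CPM in EU and 455 ± 129 in PBS (SD, n = 3; exact permutation p = 0.1), and 18 passed when adjusted over the list alone. EU replicate 2 stood apart at 1612 CPM against 840 and 774 in EU replicates 1 and 3. With the 10 members at 0 in PBS set to their bound, the median log2 fold went from 1.79 to 1.57. Hist1h4d measured 62.6 ± 15.9 CPM in EU with no count in PBS, at least 41.1-fold higher against the floor of 3 counts over the group, and Hist1h1e measured 112 ± 38.6 and 22.0 ± 15.6 CPM. Near-identical histone copies can share reads, so values of single members are uncertain. Cell cycle genes were higher with 27 of 29 positive and none passing over the list alone (median 1.48 above all genes, adjusted p = 0.017; adjusted p = 0.721 with an estimated correlation). The same library, EU replicate 2, stood apart at 2150 CPM summed over this list, where EU replicate 3 held 582 CPM and the PBS libraries 343 to 421. Without EU replicate 2 the adjusted p was 0.072, and without PBS replicate 1, PBS replicate 2 or PBS replicate 3 it was 0.249, 0.515 or 0.299. Mki67, the proliferation marker, measured 210 ± 198 CPM in EU and 50.4 ± 37.5 in PBS.

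**Figure D2:**
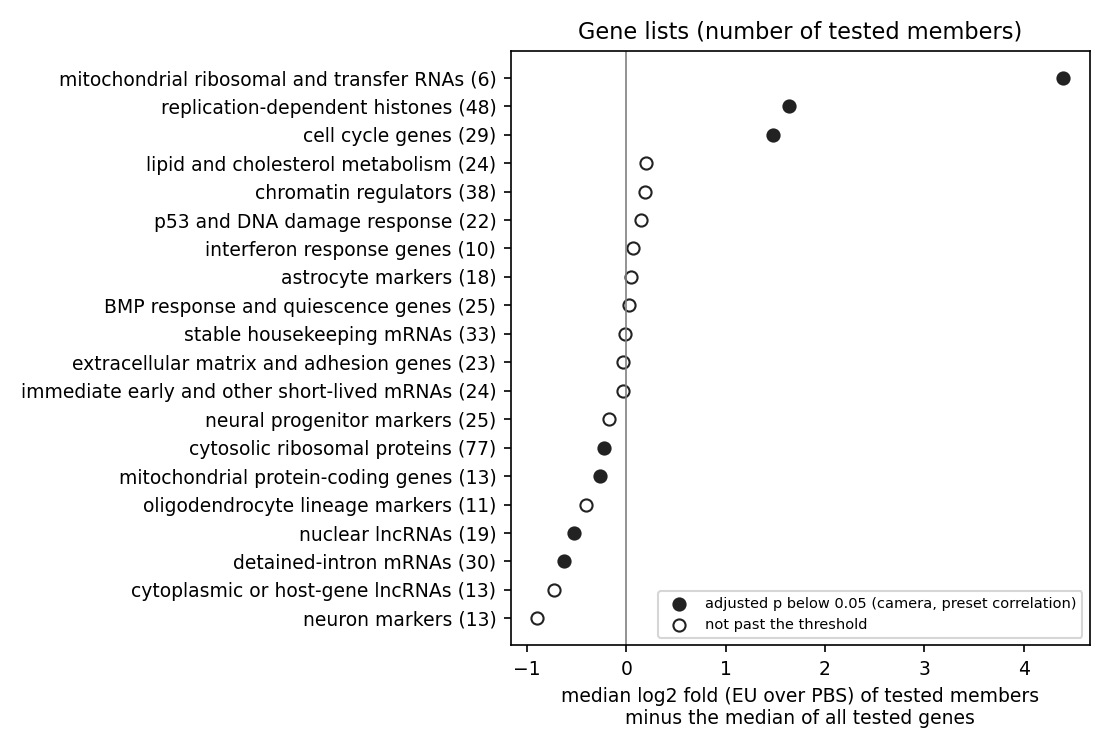
Points give, for each of the 20 tested gene lists, the median log2 fold of its tested members in EU over PBS minus the median of all tested genes (horizontal axis), with the number of tested members in brackets. Filled points passed camera with a preset correlation, and the lists farthest to the right are the mitochondrial ribosomal and transfer RNAs, the replication-dependent histones and the cell cycle genes.

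**Figure D3:**
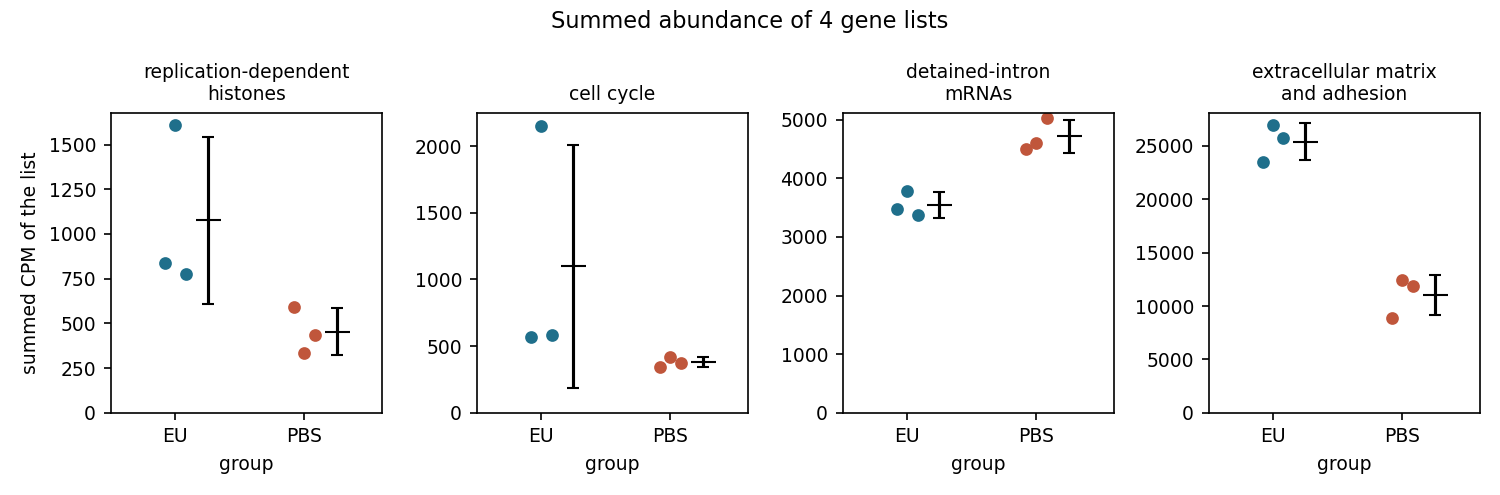
Points give the summed CPM of a gene list in each library (vertical axis, from 0) for 3 EU and 3 PBS libraries (horizontal axis), with the mean and SD of each group as a black bar. EU and PBS do not overlap in any of the 4 lists, and 1 EU library stands far above the others for cell cycle genes.

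The remaining tested lists did not pass camera. Extracellular matrix and adhesion genes had 13 of 23 members positive (camera adjusted p = 0.740, 3 passing higher over the list alone), yet their summed abundance was 25410 ± 1761 CPM in EU and 11070 ± 1884 in PBS (SD, n = 3; exact permutation p = 0.1), most of it Ncan. Chromatin regulators summed to 6914 ± 469 and 5487 ± 442 CPM (29 of 38 positive, camera adjusted p = 0.919). Stable housekeeping mRNAs summed to 15110 ± 531 and 12660 ± 933 CPM (camera adjusted p = 0.260), and immediate early and other short-lived mRNAs to 844 ± 89.0 and 850.5 ± 163 CPM (camera adjusted p = 0.631). BMP response and quiescence genes had 16 of 25 members positive (camera adjusted p = 0.614), lipid and cholesterol metabolism genes 15 of 24 (0.640) and p53 and DNA damage response genes 15 of 22 (0.6). In each of these 3 lists, 3 members passed higher over the list alone. Interferon response genes had 7 of 10 positive (camera adjusted p = 0.631) and cytoplasmic or host-gene lncRNAs 5 of 13 (0.631), although this last list was called lower without EU replicate 1 (0.021), EU replicate 2 (0.010) or EU replicate 3 (0.011). Among markers of cell types, neural progenitor markers had 12 of 25 members positive (camera adjusted p = 0.279), astrocyte markers 12 of 18 (0.251), neuron markers 6 of 13 (0.631) and oligodendrocyte lineage markers 4 of 11 (0.456, 1 passing higher over the list alone). The quiescence, lipid and astrocyte lists had medians 0.03, 0.20 and 0.05 above that of all genes and a downward test. The extracellular matrix list had a median 0.03 below that of all genes (-0.03) and an upward test. The 5 lists with fewer than 5 tested members have values only. Small nuclear and nucleolar RNAs summed to 53.6 ± 22.2 CPM in EU and 33.2 ± 23.5 in PBS, and other Pol III and ribozyme RNAs to 20.9 ± 16.8 and 70.9 ± 84.7 (SD, n = 3 each). Nuclear ribosomal RNA genes summed to 0.671 ± 0.245 and 11.1 ± 19.3 CPM, microglia and macrophage markers to 19.7 ± 1.66 and 7.45 ± 8.00, and vascular and fibroblast markers to 10.4 ± 2.198 and 13.5 ± 16.03 (SD, n = 3 each). All PBS counts of the 13 ribosomal RNA genes, of which 0 were tested, lay in PBS replicate 1 (33.4 CPM). That library also held most of the vascular PBS value, at 31.8 CPM against 2.13 and 6.44. IDs without a symbol, such as the most abundant gene, cannot enter these lists. The ribosomal sum is therefore no measure of all nuclear ribosomal RNA.

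Among annotation classes, processed pseudogenes took a smaller share of EU than of PBS counts, 0.248% ± 0.034 against 0.578% ± 0.116 (SD, n = 3; exact permutation p = 0.1, adjusted over 10 classes 0.25). Their median log2 fold lay 1.42 below that of all genes (-1.42; 234 of 307 negative, camera adjusted p = 1.7e-21; adjusted p = 0.118 with an estimated correlation). Other pseudogenes held 0.053% ± 0.0034 and 0.178% ± 0.018 (camera adjusted p = 0.0080; adjusted p = 0.181 with an estimated correlation). Of 47 tested members 25 were negative and 22 positive, and a few models held much of the PBS share. The class summed to 1687 ± 221 CPM in PBS, of which Gm10925 took 256 ± 67.0, Gm28439 201 ± 25.6 and Gm28661 198 ± 37.4. In EU these models measured 21.3 ± 15.5, 14.7 ± 11.4 and 20.6 ± 15.9 CPM. Unscaled counts in EU replicates 1 to 3 did not follow the library totals, at 309, 302 and 309 for Gm10925. The low mitochondrial gene mt-Atp6 held 245, 224 and 300. Whether these pseudogene models and the low mitochondrial genes share reads was not tested, so they may not be separate results. Genes of the class TEC, loci that still await experimental checking, were higher with 286 of 473 positive (camera adjusted p = 9.2e-14), and this call alone among the classes held with an estimated correlation (adjusted p = 0.016). Of the 473, 130 had no PBS count and were tested only through their EU counts, against 691 of all 12477 tested genes. Among protein-coding genes 6387 of 11085 were positive. The TEC call was lost without EU replicate 1 (adjusted p = 0.927), EU replicate 2 (0.989) or EU replicate 3 (0.695), and the class took 0.362% ± 0.044 of EU counts and 0.361% ± 0.048 of PBS counts. Long noncoding RNAs were called higher by camera (adjusted p = 0.0080; adjusted p = 0.119 with an estimated correlation) although their median lay 0.10 below that of all genes (-0.10, mean log2 fold 1.09). Of 492 tested lncRNAs, 70 had no PBS count. Without EU replicate 1, EU replicate 2 or EU replicate 3 that class was called lower (adjusted p = 1.4e-04, 0.0015 and 4.1e-04). Genes with no annotation match were called lower (adjusted p = 1.5e-05; adjusted p = 0.181 with an estimated correlation), and their call and that of other pseudogenes were lost without PBS replicate 1 (0.141 and 0.104), PBS replicate 2 (0.187 and 0.125) or PBS replicate 3 (0.056 and 0.222). Protein-coding genes were not called (adjusted p = 0.333), with shares of 71.9% ± 7.49 and 72.7% ± 3.66. Without EU replicate 1, EU replicate 2 or EU replicate 3 they were called higher (3.3e-12, 5.6e-07 and 6.9e-09) and without PBS replicate 1, PBS replicate 2 or PBS replicate 3 lower (0.0057, 0.013 and 0.0065). These class changes followed the group of the library left out, and the low-count filter then kept other genes. A filter at a mean of 5 CPM on all 6 libraries also turned lncRNAs (camera adjusted p = 0.053) and protein-coding genes (2.3e-05). It lost the TEC call (0.280), so the effect of a library cannot be told from that of the filter.

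The relation of fold to gene length was weak and depended on the low-count filter. The median log2 fold was 0.01 among the 2489 genes of shortest genomic span and 0.27 among the 2488 of longest (Spearman correlation 0.082 across 12441 genes, which are not independent replicates). The correlation was 0.108 with the number of uridines in the longest annotated transcript, and 0.172 for span among 3419 genes at a mean of at least 50 CPM, but for span without a low-count filter it was -0.126. With exonic length it was 0.092 over all genes and 0.205 at a mean of at least 50 CPM. With the length of the longest transcript it was 0.121 and 0.262. Without PBS replicate 1, PBS replicate 2 or PBS replicate 3 the correlation with span was 6.9e-05, 0.0062 or -0.0020, and without EU replicate 1, EU replicate 2 or EU replicate 3 it was 0.162, 0.162 or 0.155. These values followed the group of the library left out, for which the low-count filter was redone. With all libraries and a filter at a mean of 5 CPM the correlation with span was 0.176.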

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

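The alternatives below were run on 3 libraries against 3, in which PBS replicates vary far more than EU replicates, and the cause of each change was not tested. Values for lists and classes are adjusted p-values of limma's camera unless fry is named, and for the length trend Spearman correlations with genomic span. Over all named genes and settings the call stayed the same in 1529 cases, in 46 of which the fold of an uncalled gene changed sign, and became stronger in 181 and weaker in 13. In 21 cases, all with unscaled counts, a gene that was not called before was called against the sign of its earlier fold. With the replicate number as a block, edgeR called 144 genes higher and 50 lower, 124 and 45 of them by a log2 fold of at least 1, and the length trend turned to -0.014. Deviations from the group mean correlated between libraries of the same number at 0.074, 0.051 and 0.034 over 12477 tested genes, all below the 0.1 used as the bar, and at 0.165, 0.161 and 0.110 over 3424 genes at a mean of at least 50 CPM, all above it. In both sets each library correlated best with its own number, a hint from the data and not from the labels, so whether equal numbers were pairs stays open. With library size alone edgeR called 3 higher and 34 lower, all by a log2 fold of at least 1. Without a low-count filter it called 82 higher and 262 lower (79 and 262 by a log2 fold of at least 1). The camera adjusted p was 0.367 for cell cycle genes, 0.414 for genes with no annotation match, whose direction turned, and 0.167 for other pseudogenes, and the length trend turned to -0.126. At a mean of at least 5 CPM the camera adjusted p was 0.090 for cytosolic ribosomal proteins, 0.280 for TEC genes, and, with the direction turned, 0.053 for lncRNAs and 2.3e-05 for protein-coding genes, and the length trend was 0.176. DESeq2 called 506 higher and 438 lower (438 and 361 by a log2 fold of at least 1) and limma-voom 214 and 25, all by at least 1.

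With an estimated correlation the camera adjusted p was 0.354 for nuclear lncRNAs, 0.645 for mitochondrial protein-coding genes, 0.238 for mitochondrial ribosomal and transfer RNAs, 0.518 for cytosolic ribosomal proteins and 0.527 for histones. It was 0.238 for detained-intron mRNAs and 0.721 for cell cycle genes. For classes it was 0.119 for lncRNAs, 0.181 for genes with no annotation match and for other pseudogenes, and 0.118 for processed pseudogenes. With fry of limma the adjusted p was 0.092 for mitochondrial protein-coding genes, 0.399 for genes with no annotation match and 0.156 for processed pseudogenes. Chromatin regulators (0.041), p53 and DNA damage response (0.0019), interferon response (0.041) and extracellular matrix genes (0.0019) were called higher by fry. Fry asks whether the folds of a list differ from 0, whereas camera compares them with those of other genes. Protein-coding genes as a class, 11085 tested, were also called higher by fry, so these calls do not set a list apart. The direction by fry differed from that of camera for cytosolic ribosomal proteins (0.440), short-lived mRNAs (0.030), other pseudogenes (0.868) and protein-coding genes (2.4e-04).

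Leaving out each library, with the low-count filter redone each time, edgeR called 0 to 10 genes lower, with the same range by a log2 fold of at least 1. Camera adjusted p-values ran from 0.013 to 0.124 for nuclear lncRNAs, 0.010 to 0.978 for cytoplasmic or host-gene lncRNAs, 0.014 to 0.086 for mitochondrial ribosomal and transfer RNAs (3 settings), 0.0023 to 0.442 for cytosolic ribosomal proteins and 1.6e-04 to 0.515 for cell cycle genes. For classes they ran from 7.0e-05 to 0.0015 for lncRNAs, 2.2e-04 to 0.187 for genes with no annotation match (4 settings), 3.2e-12 to 0.222 for other pseudogenes, 3.3e-12 to 0.013 for protein-coding genes and 2.8e-16 to 0.989 for TEC genes. The length trend ran from -0.0020 to 0.162.

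The settings that follow were chosen after seeing the data. With unscaled counts edgeR called 12174 genes higher and 1 lower, all by a log2 fold of at least 1. This scaling moved the median log2 fold of all genes to 5.09. The 21 named genes with a negative fold before that were then called higher had log2 folds as follows: Miat 3.299, Luc7l3 3.54, Ogt 3.87, Rsrp1 3.34, Aqp4 3.75, Jun 3.78, Klf2 2.60, Gas5 3.45, Gja1 3.56, Nr2e1 3.20, Xist 4.37, Rpl4 4.37, Neat1 2.84, Snhg6 3.10, Dcx 2.69, Kdr 3.24, Ifit3 3.62, mt-Nd5 4.74, Sox2 4.72, Acta2 4.38 and Snord17 4.21. Camera adjusted p-values were then 0.057 for nuclear lncRNAs, 0.449 for mitochondrial ribosomal and transfer RNAs, 0.716 for cytosolic ribosomal proteins and 0.126 for detained-intron mRNAs, and the direction turned for lncRNAs (1.7e-05), protein-coding genes (6.8e-17) and TEC genes (0.0051). With all libraries thinned to the smallest total edgeR called 1 higher and 9 lower, all by a log2 fold of at least 1. The camera adjusted p was then 0.319 for nuclear lncRNAs and 0.137 for cytosolic ribosomal proteins. The direction turned for lncRNAs (0.157) and protein-coding genes (3.3e-05), the length trend was 0.141 and the ratio of genes with 10 counts was 0.958. At a mean of at least 50 CPM edgeR called 1 higher and 8 lower, all by a log2 fold of at least 1. The camera adjusted p was then 0.212 for nuclear lncRNAs and for mitochondrial protein-coding genes and 0.217 for cytosolic ribosomal proteins, the direction turned for lncRNAs (0.084) and protein-coding genes (7.0e-04), and the length trend was 0.176. Limma-voom with group weights called 668 higher and 31 lower, all by a log2 fold of at least 1. As summed counts, nuclear lncRNAs were 1.26 times and mitochondrial protein-coding genes 1.11 times as high in EU as in PBS, against the direction of their calls.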

Other observations

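The tests of satellite-like models, of genes without PBS counts and of the number of genes called were chosen after the result was seen, the others before. After their first values were seen, 2 tests were changed. The genomic DNA value went from the lower of 2 gene sets to the chemoreceptors alone. The loss of transcripts was matched in finer expression groups. Neither change altered the outcome of its test. An interval for list medians was also added late, and it opened the reading on short-lived RNA. Among genes singled out after their values were seen, Hlf, a transcription factor gene, measured 315 ± 104.1 CPM in EU and 66.8 ± 8.82 in PBS, and the creatine kinase gene Ckb 5352 ± 780 and 2316 ± 459 CPM (SD, n = 3 each; edgeR adjusted p = 0.098 and 0.103). In the other direction Wsb1 measured 87.6 ± 27.2 and 331 ± 88.7 CPM, and the mRNA export factor gene Nxf1 41.4 ± 4.40 and 113 ± 23.6 CPM (edgeR adjusted p = 0.103 each). Thinned to 413181 counts, PBS replicate 2 held 22 genes and PBS replicate 1 held 3 genes with at least 10 counts that had no count in any other library, while PBS replicate 3 and the 3 EU libraries held 0 such genes (exact permutation p = 0.4). Of the 22 genes, 5 were chemoreceptor genes.

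The satellite-like gene models were higher in PBS, at 1881 ± 579 CPM summed against 9.21 ± 3.76 in EU, without TMM factors. The longest transcript of Gm10718 matches itself best at a shift of 234 bases, at 62.6% of positions. That of Gm10800, which held most of the counts, does so at 225 bases (56.3%) and that of Gm10801 at 231 bases (52.75%). Transcripts outside the family were not scored for comparison. A difference in total counts is argued against, since the lowest unscaled PBS sum was 4.07 times the highest EU sum. A move of reads among the 11 models is argued against too, since their summed share was 117 times higher by the same measure. Reads moved to or from copies outside these models are not in the sum, so such a move was not tested. Genomic DNA that passed the DNase step may contribute and cannot be told apart: the share of 1779 chemoreceptor genes was 1.88 times higher in the lowest PBS library than in the highest EU library, but a second set of 350 tissue-restricted genes had only 1, 0 and 12 PBS counts. Satellite RNA that binds beads without label was not tested.

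Of the tested genes, 691 had counts in EU and none in any PBS library. EU libraries thinned to the smallest total left 95.4 tested genes at 0 in every EU library on average over 20 draws, 7.24 times fewer. This cannot decide on depth, because a gene without PBS counts was tested only if its EU counts were high enough. Over all genes, thinned libraries held a count for 13525 ± 189 genes in EU and 10727 ± 415 in PBS. Depth alone therefore does not account for the lower number of genes detected per PBS library. Independent loss of transcripts in each PBS library gave 549 genes on average and at most 635 over 1000 draws. The observed number was 1.26 times the mean of the draws, so that loss may account for much of it. The excess cannot reject independent loss, since the draws gave all genes of an expression group 1 rate. A gene without PBS counts also passes the low-count filter only through its EU counts, which the draws ignore. Whether retention of labelled RNA adds to the number stays open.

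The lower share of detained-intron mRNAs in EU was not matched by random lists of the same mean expression, among which its median fell at percentile 0.01, the smallest that 10000 lists can give, nor by lists also matched on transcript length and GC content, again at percentile 0.01. The bootstrap interval of its median over members, -0.65 to -0.197, ended below percentile 2.5 of the matched lists, which lay at -0.12 for expression and, narrowly, at -0.192 with length and GC. Loss of short-lived RNA over the 7 days could be neither shown nor excluded: the median of immediate early and other short-lived mRNAs fell at percentile 32.1 of their matched lists, but its bootstrap interval ran from -0.76 to 0.66. Matched lists take no account of genes that vary together. The camera call was lost with an estimated correlation (adjusted p = 0.238), which was 0.035 for this list. Lists with estimates below the preset lost their calls as well, so this loss does not show that the members vary together. A candidate explanation that stays open is that these RNAs bind beads without label more than other RNAs do.

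The 10 splits of the 6 libraries into 3 and 3 are too few for a share below 0.05. The real split called 3 genes and the highest other split 0, 7 lists against 5, and 5 classes against 3; in each case 1 split, the real one, reached the real number.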
